A study of Mus musculus with 6 samples.

How the data were processed

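Total RNA from mouse lung was extracted with Trizol, labelled by a whole-transcript sense-target method and hybridised to Affymetrix arrays, per the labels' protocols. Groups were taken from the genotype given in the labels: 3 wild-type and 3 Scnn1b-transgenic (Scnn1b-Tg) samples, all of lung and of 1 genetic background. No batch, age or sex is given in the labels, so no batch could be tested.

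The deposited values are intensities per probe set on a linear scale, 1 column per sample, made with RMA per the submitters' processing notes. Its version and settings are not given in the sources used here. That the scale is linear was read from the values, which have medians between 47.6 and 48.5 and no negative values. The lowest intensity on each array was 18.3 to 18.6, and 16.1% of genes had a mean intensity under 25. Whether a constant was added before deposit is not given in the sources used here. If one was, log2 fold changes of dim genes are smaller than those of the signal above it, and the fold changes printed are of the values as deposited.

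Of 28815 probe sets, 21780 had exactly 1 gene symbol in the platform annotation, 1605 had several and 5430 were not listed there. Through their Entrez identifiers 21689 of the named probe sets matched a mouse RefSeq gene table, and 0 symbols needed an update. Probe sets with several symbols or none were left out, and for the 998 genes with more than 1 probe set the brightest over all arrays was taken, which left 19935 genes. For 3 named genes with a further probe set, that probe set gave a smaller log2 fold change: Cd80 (0.10 against 0.26), Ciart (-0.07 against -0.31) and Top2a (0.0052 against 0.44). Genomic positions were not used here.

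Log2 intensities were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, genotype as the only term, 4 residual degrees of freedom and 6.99 after moderation). Tests were two-sided with Benjamini-Hochberg adjustment over all genes, a gene was called at an adjusted p under 0.05, and a log2 fold change of 1 or more counted as 2-fold. Errors of log2 fold changes are the standard errors of this fit, and errors of intensities are the SD of 3 arrays. A total of 38 gene lists (cell type markers, immune states, proteases, matrix and stress responses) was fixed, with the designs, alternatives and naming rule, before the data were examined. Of their 742 entries 688 were measured. Some genes stand on several lists, so the lists are not independent of each other. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Camera compares a list with all other genes, while fry asks whether its genes move one way on balance. List values in the text are mean log2 fold changes over members, and members were also counted with p adjusted over the list alone.

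Genes were named by a rule: the sodium channel subunits, Mmp12, the 12 largest rises and 10 largest falls among called genes whose groups do not overlap (or, where under 5 passed in a direction, the 5 smallest p-values of that direction), and for each list up to 3 called members or, where none was called, the 2 with the largest absolute log2 fold change. Predicted genes without a name were passed over among the largest changes. Since only Scnn1b was called, the rest of the named genes are given as values.

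Alternatives were quantile normalization, median centring, leaving out the 6645 dimmest genes, the mean over probe sets of a gene, all probe sets, an intensity trend with robust variance, array weights, a block for the replicate number, and each array left out in turn. A pair of alternatives was added after seeing the data: subtracting 16 from every intensity before log2, and leaving out both wild type replicate 2 and Scnn1b-Tg replicate 3. The fit was tested on simulated data for this comparison, with 19935 genes at the means of the real ones and with variances drawn from the fit, 200 of them changed and 5 lists shifted by 0.3, in 20 runs. Of genes changed by 0.5 on the log2 scale 77.4% were recovered, of those changed by 1 98.9%, by 2 99.9% and by 3 100%, with 9.15 false calls among 217 calls per run. All shifted lists were recovered (100%) and 0 lists without a shifted gene were called. In this simulation genes vary independently of each other, which genes of 1 cell type in real tissue do not. The shares hold for 200 changed genes drawn at random, and the adjusted threshold is stricter where fewer genes change. In the real data 14 genes were at least 2-fold higher, and of these only Scnn1b was called. The shares therefore do not show that a gene left uncalled changed less than 2-fold.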

Results

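Whole-lung RNA was compared between wild-type mice and mice with a transgene for Scnn1b, all of the C57BL/6 background. Scnn1b encodes the β subunit of the epithelial sodium channel, which takes up sodium across airway surfaces. The stated purpose was to look for genes with a part in emphysema, the loss of alveolar walls. There were 6 arrays, 3 of wild type and 3 of Scnn1b-Tg, each with an RMA intensity for 28815 probe sets. Array medians lay between 47.6 and 48.5, and the lowest value of each array between 18.3 and 18.6. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.9909 to 0.9965 within a genotype and 0.9898 to 0.9944 between genotypes. The first principal component (34.0% of the variance) set wild type replicate 2 apart at 16.3, with the other arrays between -8.91 and 5.46. On it the 3 transgenic arrays (-8.91 to -4.48) lay below the 3 wild-type arrays, of which replicate 1 (-3.28) was close to them. The second (22.6%) set Scnn1b-Tg replicate 3 apart at 13.3, with the others between -8.03 and 2.47. Nothing in the labels says that the 3 samples of a genotype came from separate animals, so p-values measure the spread between these samples, and the number of arrays limits the precision.

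Scnn1b itself rose 10.3-fold in Scnn1b-Tg lung. Its mean intensity was 139.7 ± 31.9 (SD, n = 3) in wild type and 1422 ± 98.3 (SD, n = 3) in Scnn1b-Tg. The log2 fold change was 3.37 ± 0.16 (SE), with an adjusted p of 0.00241 in limma, and all 3 transgenic arrays lay above all 3 wild-type arrays. The genes of the other channel subunits gave log2 fold changes of -0.12 ± 0.09 for Scnn1a and -0.09 ± 0.10 for Scnn1g, with adjusted p-values of 0.929 and 0.975. Over single arrays left out they ran from -0.21 to -0.02 and from -0.16 to 0.0012. As a list, the 3 subunits had a mean log2 fold change of 1.05 but a median of -0.09, and camera gave an upward direction with an adjusted p of 0.178 (adjusted p = 0.511 with an estimated correlation). Over 16 alternatives the adjusted p of this list ran from 0.0418 to 0.339 and 1 passed. Without wild type replicate 3 the log2 fold change of Scnn1b was 3.38 with an adjusted p of 0.0559, and over all alternatives its adjusted p ran from 1.18e-06 to that value.

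**Figure D1:**
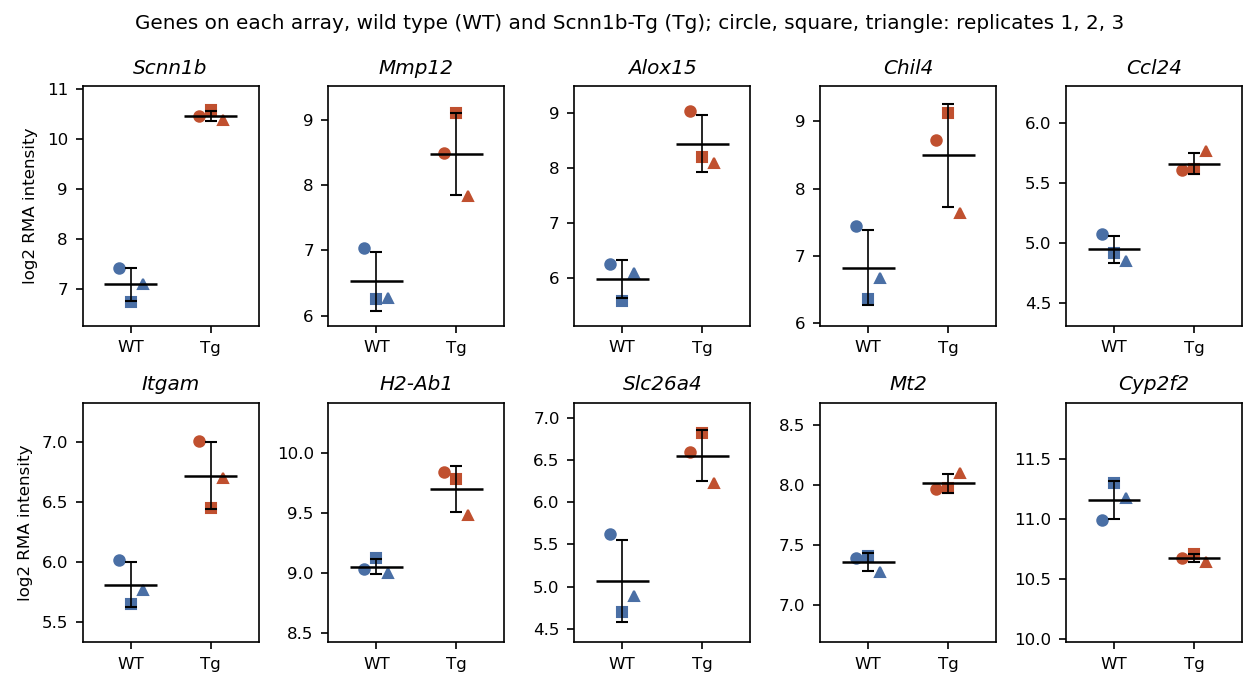
Log2 RMA intensity of 10 genes on each of the 6 arrays, with wild type (WT) in blue, Scnn1b-Tg (Tg) in red, a horizontal line for the mean and bars for the SD of 3 arrays. The 3 Scnn1b-Tg arrays lie above the 3 wild-type arrays for Scnn1b, Mmp12, Alox15, Chil4, Ccl24, Itgam, H2-Ab1, Slc26a4 and Mt2, and below them for Cyp2f2, while only Scnn1b passed the test over all genes. These genes were picked for display, and over all genes the groups were separate for 10.7%, against 10% by chance. Each panel has its own vertical range.

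Scnn1b was the only gene past the threshold among the 19935 tested with limma, so that 1 gene was higher and 0 were lower, and the same gene was the only one changed at least 2-fold. After Scnn1b, the smallest p-values among higher genes belonged to Mt2, a metallothionein that binds zinc and copper (log2 fold change 0.65 ± 0.06, SE), and Ccl24, a chemokine that attracts eosinophils (0.72 ± 0.07). Next came Fcgr2b, the inhibitory IgG receptor (0.55 ± 0.06), and Alox15, a lipoxygenase of alternatively activated macrophages and eosinophils (2.46 ± 0.27, 5.50-fold). Each of these 4 had an adjusted p of 0.109. Among lower genes the smallest p-values belonged to Tspan12, a tetraspanin (-0.42 ± 0.06, adjusted p = 0.129), and Tmem35a (-0.30 ± 0.05, adjusted p = 0.169). They were followed by Cyp2f2, a club cell cytochrome P450 (-0.48 ± 0.08, adjusted p = 0.205), Gimap6 (-0.40 ± 0.07, adjusted p = 0.225) and Gtf2e2 (-0.26 ± 0.05, adjusted p = 0.225). At an unadjusted p under 0.05 there were 789 higher and 409 lower genes, together 6.01% of those tested. The 3 arrays of a genotype lay wholly above those of wild type for 1248 genes and wholly below for 879, or 10.7% of genes against 10% by chance. At any p, 14 genes were at least 2-fold higher and 0 at least 2-fold lower. The count of called genes was 39 (38 higher, 1 lower) with the 6645 dimmest genes left out, 36 with an intensity trend and robust variance, and 23 with 16 subtracted from every intensity, the last chosen after seeing the data. It was 0 without wild type replicate 3, 5 without Scnn1b-Tg replicate 3, and 6 without both arrays that stood apart, again chosen after seeing the data.

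Of the 38 gene lists, camera with its preset correlation called 17, of which 14 were higher and 3 lower in Scnn1b-Tg lung. With an estimated correlation 0 lists were called, and that adjusted p is given below with each list that camera called. With fry, a self-contained test, 7 lists were called, all higher, and 5 of them were among the 17: alternatively activated macrophage, macrophage, other matrix-degrading proteases, chemokines and MHC class II. The other 2 fry calls were protease inhibitors and the sodium channel subunits. Of the 3 subunits measured only Scnn1b was higher, so the call of that list rests on the gene of the transgene itself. The 9 other splits of the 6 arrays gave between 3 and 14 called lists.

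Genes of alternatively activated macrophages had the largest mean among the lists that camera called. All 19 measured members were higher in Scnn1b-Tg, by a mean log2 fold change of 0.68 and a median of 0.40 (camera adjusted p = 3.87e-19; adjusted p = 0.0510 with an estimated correlation). None passed over all genes tested, 12 passed adjusted over the list alone, and the arrays of each genotype were fully separate for 14. Alox15 went from an intensity of 64.5 ± 14.5 (SD, n = 3) to 364 ± 138, and Chil4, a chitinase-like protein, from 119 ± 48.1 to 392 ± 179, a log2 fold change of 1.67 ± 0.41 (SE). The mean deviation of the list was between -0.39 and -0.24 on the wild-type arrays and between 0.17 and 0.45 on the transgenic arrays, lowest among these on replicate 3. In the general macrophage list 14 of 19 members were higher, with a mean of 0.22 (adjusted p = 4.77e-06; adjusted p = 0.0769 with an estimated correlation), and 8 passed adjusted over the list alone. Itgam, the CD11b integrin chain, gave 0.91 ± 0.15 and Adgre1, the F4/80 antigen, 0.76 ± 0.17. The lipid-laden and lysosomal macrophage list had 17 of 20 members higher and a mean of 0.16 (adjusted p = 1.91e-06; adjusted p = 0.0914 with an estimated correlation), with 5 past the threshold adjusted over the list alone. Its members with the largest values were Gpnmb, a membrane glycoprotein of lipid-loaded macrophages (0.41 ± 0.07), and Fabp4, a fatty acid binding protein shared with fat cells (0.76 ± 0.36), which on Scnn1b-Tg replicate 3 lay 1.56 above the mean of the other arrays and without that array was 0.31. The classically activated macrophage list was not called by camera with its preset correlation, with 11 of 16 members higher, a mean of 0.07 (adjusted p = 0.0559; adjusted p = 0.352 with an estimated correlation), and 0 past the threshold adjusted over the list alone. It passed in 7 of 16 alternatives, with adjusted p-values from 0.0127 to 0.313. Its largest values were 0.26 ± 0.06 for Cd80 and 0.20 ± 0.14 for Ptgs2, which ran from 0.07 to 0.32 over single arrays left out.

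By camera with its preset correlation, genes of type 2 immunity, chemokines and antigen presentation were also shifted upward. In the type 2 immunity and eosinophil list 16 of 20 members were higher with a mean of 0.35 (adjusted p = 6.93e-07; adjusted p = 0.236 with an estimated correlation), and 6 passed adjusted over the list alone. Besides Alox15, Ccr3, the eotaxin receptor of eosinophils, had the largest value at 1.40 ± 0.32 (SE), and its intensity was 47.4 ± 4.08 (SD, n = 3) in wild type and 135 ± 62.4 in Scnn1b-Tg. The median of the type 2 list was lower than its mean, at 0.12, and fry did not call it (adjusted p = 0.0557). Some members, picked after their values were seen, lay near 0: Il4 (0.06 ± 0.06), Il5 (0.05 ± 0.05), Il13 (0.09 ± 0.08) and Epx (0.07 ± 0.05). Of 31 chemokines 22 were higher, with a mean of 0.20 (adjusted p = 1.98e-06; adjusted p = 0.0769 with an estimated correlation), and 5 passed adjusted over the list alone. The leading members were Ccl9 at 0.80 ± 0.10 and Ccl17, a ligand of CCR4 on T cells, at 0.77 ± 0.14. In the MHC class II list 12 of 14 members were higher, with a mean of 0.30 and a median of 0.28 (adjusted p = 3.08e-10; adjusted p = 0.0769 with an estimated correlation). Here 6 passed adjusted over the list alone, among them the class II β chain H2-Ab1 (0.65 ± 0.10) and the invariant chain Cd74 (0.62 ± 0.08). H2-Ab1 had an adjusted p of 0.151 over all genes and of 0.0448 without Scnn1b-Tg replicate 3. Over all alternatives its adjusted p ran from 0.0225 to 0.623. The neutrophil list was not called (11 of 18 higher, mean 0.12, adjusted p = 0.217; adjusted p = 0.656 with an estimated correlation), although Retnlg gave 1.38 ± 0.35 and Mmp9 0.30 ± 0.08. In 2 of 16 alternatives the neutrophil list passed, 1 of them without Scnn1b-Tg replicate 2 (adjusted p = 0.0316), and the adjusted p ran from 0.0280 to 0.976. Nor were the mast cell and basophil list (9 of 14 higher, mean 0.03, adjusted p = 0.441), led by Hdc at 0.23 ± 0.07 and Cpa3 at 0.12 ± 0.06, or the T and NK cell list (14 of 22 higher, mean 0.05, adjusted p = 0.331), led by Il7r at 0.41 ± 0.09 and Icos at 0.30 ± 0.10. Interferon response genes gave 11 of 17 lower with a mean of -0.03 (adjusted p = 0.441), with -0.20 ± 0.17 for Gbp3 and -0.17 ± 0.06 for Ifit2. Gbp3 ran from -0.35 to -0.03 over single arrays left out, and the interferon mean turned to 0.02 without wild type replicate 2. The adjusted p ran from 0.0413 to 0.843 over 16 alternatives, and 1 passed.

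For proteases and matrix, the groups closest to the stated question, Mmp12, the macrophage elastase, had the largest value of all metalloproteinases. Its intensity was 95.05 ± 31.4 (SD, n = 3) in wild type and 379 ± 162 in Scnn1b-Tg, a log2 fold change of 1.95 ± 0.34 (SE) or 3.87-fold, with an adjusted p of 0.225 over all genes. The adjusted p of Mmp12 was 0.0225 with the 6645 dimmest genes left out and 0.0354 with 16 subtracted, the latter chosen after seeing the data. It was 0.499 with an intensity trend and robust variance, and reached 0.692 among the other alternatives. Of 21 metalloproteinases 12 were higher and the list was not called (mean 0.12, adjusted p = 0.681; adjusted p = 0.730 with an estimated correlation), while with the 6645 dimmest genes left out its adjusted p was 0.0254. Over the other alternatives the adjusted p of the metalloproteinase list reached 0.932. Adjusted over the list alone 2 passed, Mmp12 and the membrane-bound Mmp25 (0.46 ± 0.07). Other matrix-degrading proteases had 15 of 21 members higher and a mean of 0.14 (adjusted p = 0.000122; adjusted p = 0.0769 with an estimated correlation), with 5 past the threshold adjusted over the list alone, led by the collagenolytic cathepsin Ctsk (0.62 ± 0.13) and Adam8 (0.61 ± 0.09). Protease inhibitors were not called by camera (11 of 17 higher, mean 0.09, adjusted p = 0.191; adjusted p = 0.404 with an estimated correlation) but were called by fry (adjusted p = 0.0221), with 2 past the threshold adjusted over the list alone. Serpinb2, an inhibitor of plasminogen activators, gave 0.47 ± 0.07 and Serpina3n 0.61 ± 0.31, which without wild type replicate 1 was 0.23. The elastic fibre and collagen list had 26 of 27 members higher and a mean of 0.15 (adjusted p = 0.000288; adjusted p = 0.561 with an estimated correlation), with 0 past the threshold adjusted over the list alone. Fibronectin Fn1 gave 0.36 ± 0.15 and Ltbp2 0.33 ± 0.29, which without wild type replicate 2 were 0.17 and 0.06, and Ltbp2 was 0.69 without wild type replicate 1. Its mean deviation was -0.33 on wild type replicate 2 and 0.16 on wild type replicate 1, with the transgenic arrays between 0.05 and 0.09. Without wild type replicate 2 the mean was 0.02 (adjusted p = 0.512) and without wild type replicate 1 it was 0.27 (adjusted p = 3.50e-11).

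Among airway epithelial genes, those of club cells, the secretory cells of the distal airway, were lower in Scnn1b-Tg. Of 20 measured members 19 were lower, by a mean log2 fold change of -0.25 and a median of -0.21 (camera adjusted p = 3.53e-12; adjusted p = 0.236 with an estimated correlation), and 7 passed adjusted over the list alone. The paraoxonase Pon1 gave -0.68 ± 0.22 (SE) and the glutathione transferase Gsta3 -0.65 ± 0.20, which without wild type replicate 2 were -0.45 and -0.41. Cyp2f2 went from 2287 ± 248 (SD, n = 3) to 1630.35 ± 37.0. The mean deviation of the club cell list was 0.32 on wild type replicate 2, 0.14 on wild type replicate 3 and -0.09 on wild type replicate 1. The transgenic arrays lay between -0.18 and -0.08, so wild type replicate 1 fell within their range. Fry did not call the club cell list (adjusted p = 0.158). Without wild type replicate 2 the mean was -0.15 (adjusted p = 6.02e-07). The goblet cell and mucus list had 16 of 21 members higher and a mean of 0.13 (adjusted p = 0.00361; adjusted p = 0.117 with an estimated correlation), with 2 past the threshold adjusted over the list alone. Its largest values were 1.11 ± 0.53 for Clca1, a secreted goblet cell protein, and the negative value of Pon1, which this list also holds. Clca1 was 0.51 without wild type replicate 2 and 1.68 without wild type replicate 1. Without wild type replicate 1 the adjusted p of the goblet list was 0.0578, although its mean was no smaller at 0.14. Epithelial host defence and acute phase genes had 13 of 24 members higher and a mean of 0.13 (adjusted p = 0.0402; adjusted p = 0.352 with an estimated correlation), with 5 past the threshold adjusted over the list alone. The acute phase protein gene Saa3 gave 0.89 ± 0.22 and Reg3g, a bactericidal lectin, 0.75 ± 0.19. The host defence call ended when wild type replicate 1 or 3 or Scnn1b-Tg replicate 2 or 3 was left out, with adjusted p-values of 0.141, 0.129, 0.106 and 0.137. The list mean changed little in these fits, at 0.14, 0.12, 0.11 and 0.11. The ion and fluid transport list was not called (10 of 20 higher, mean 0.10, adjusted p = 0.638; adjusted p = 0.730 with an estimated correlation), with 1 member past the threshold adjusted over the list alone. That member was Slc26a4, the anion exchanger pendrin, at 1.49 ± 0.25, and the calcium-activated potassium channel Kcnn4 gave 0.31 ± 0.12. The ciliated cell list (15 of 23 higher, mean 0.010, adjusted p = 0.685) and the basal and squamous list (9 of 15 higher, mean 0.02, adjusted p = 0.685) were not called, and the ciliated mean turned to -0.0074 after quantile normalization and -0.011 after median centring. Their largest values were -0.21 ± 0.12 for Tppp3, 0.16 ± 0.11 for Dnah5, 0.11 ± 0.09 for Ngfr and 0.11 ± 0.10 for Aqp3. Single arrays left out brought these to -0.10, 0.07, 0.0052 and 0.0055.

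**Figure D2:**
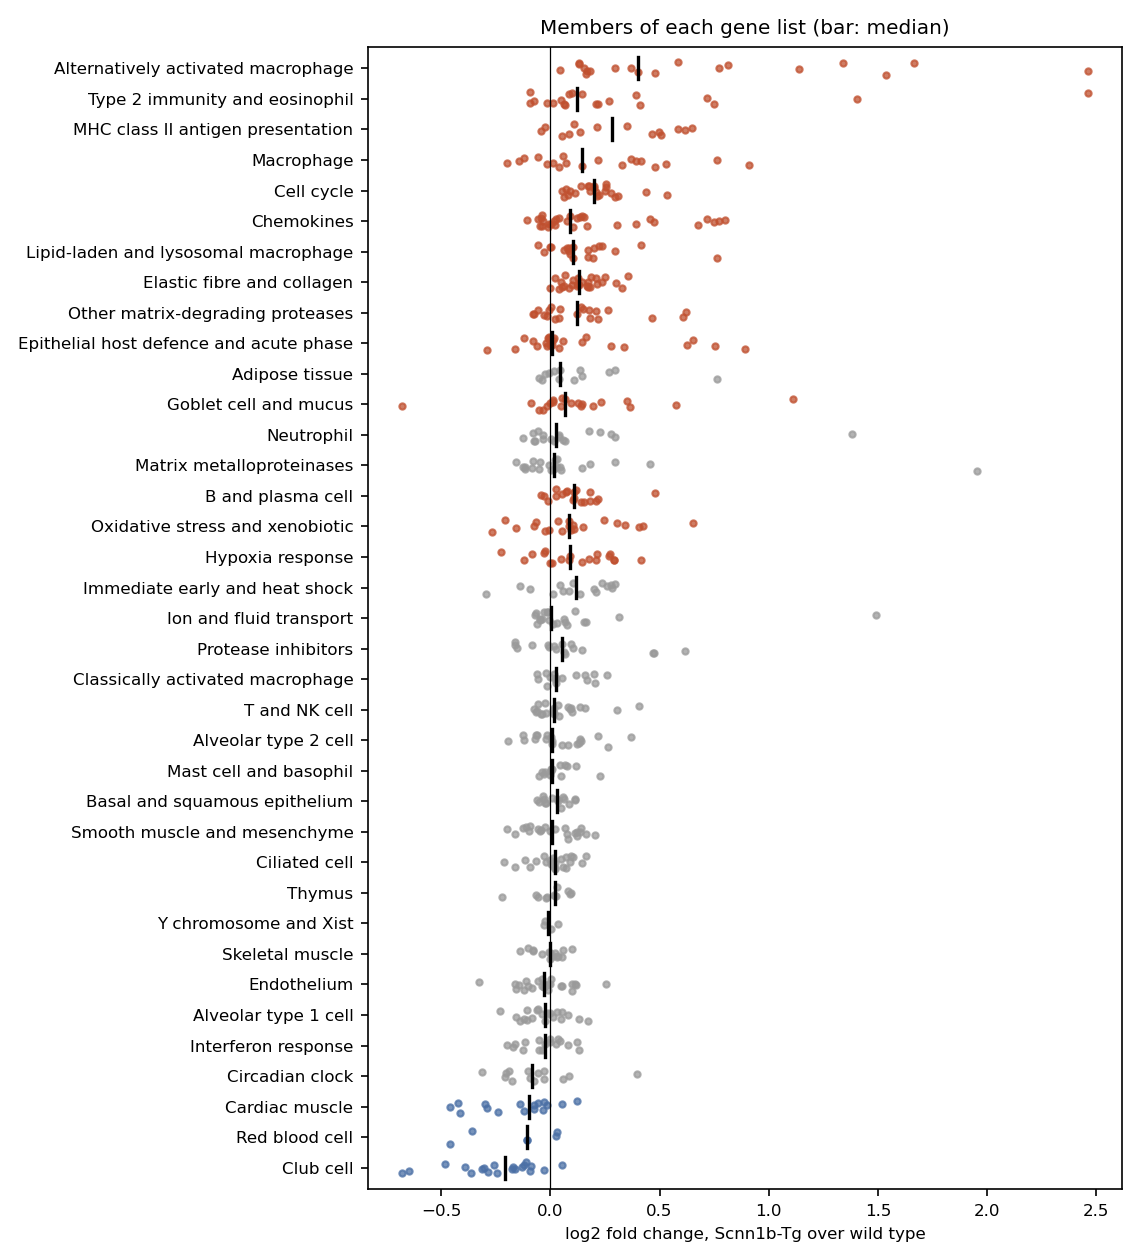
Log2 fold change (Scnn1b-Tg over wild type, horizontal axis) of every measured member of 37 gene lists, 1 point per gene, with a black bar at the median; lists that camera called with its preset correlation are red (higher) or blue (lower) and the rest grey, and the sodium channel list is not drawn. All 19 alternatively activated macrophage genes lie above 0, and 19 of 20 club cell genes lie below it.

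Among stress response lists, camera called hypoxia and oxidative stress genes as higher. Hypoxia response genes had 13 of 19 members higher and a mean of 0.11 (adjusted p = 0.000174; adjusted p = 0.0769 with an estimated correlation), with 6 past the threshold adjusted over the list alone. The prolyl hydroxylase gene Egln3 gave 0.41 ± 0.06 (SE) and Ankrd37 0.29 ± 0.10. Oxidative stress and xenobiotic genes had 14 of 21 members higher and a mean of 0.11 (adjusted p = 0.00152; adjusted p = 0.244 with an estimated correlation), with 6 past the threshold adjusted over the list alone. Mt2 went from 164 ± 8.43 (SD, n = 3) to 259 ± 13.9, and heme oxygenase Hmox1 from 93.7 ± 8.98 to 125.7 ± 10.5. Without wild type replicate 1 the adjusted p of this list was 0.0828. All 23 cell cycle genes were higher, with a mean of 0.21 (adjusted p = 1.34e-05; adjusted p = 0.561 with an estimated correlation), but 0 passed adjusted over the list alone, and Mki67 gave 0.54 ± 0.26 and Top2a 0.44 ± 0.25. These genes were at 0.23 and 0.15 without wild type replicate 2, and Top2a at 0.70 without wild type replicate 1. The mean deviation of the cell cycle list was -0.40 on wild type replicate 2 and 0.17 on wild type replicate 1, with 0.0067 to 0.16 on the transgenic arrays. Without wild type replicate 2 the cell cycle mean was 0.06 (adjusted p = 0.171), and without wild type replicate 1 it was 0.35 (adjusted p = 2.69e-14). Immediate early and heat shock genes were not called (13 of 16 higher, mean 0.10, adjusted p = 0.0885; adjusted p = 0.730 with an estimated correlation), and their mean deviation ran from -0.29 to 0.25 within wild type alone. The mean was -0.01 without wild type replicate 1 and 0.26 without wild type replicate 2. This list passed in 6 of 16 alternatives, with adjusted p-values from 3.35e-06 to 0.930. Klf4 gave 0.30 ± 0.14 and Hspa1a -0.29 ± 0.37, with ranges over single arrays left out of 0.17 to 0.45 and -0.63 to 0.18. Circadian clock genes were not called either (11 of 14 lower, mean -0.07, adjusted p = 0.0748; adjusted p = 0.517 with an estimated correlation), with 0.40 ± 0.20 for Nfil3 (0.17 without wild type replicate 2) and -0.31 ± 0.11 for Ciart. The circadian mean turned to 0.02 without wild type replicate 2, on which its mean deviation was 0.20. Circadian genes passed in 5 of 16 alternatives, with adjusted p-values from 0.0198 to 0.916.

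**Figure D3:**
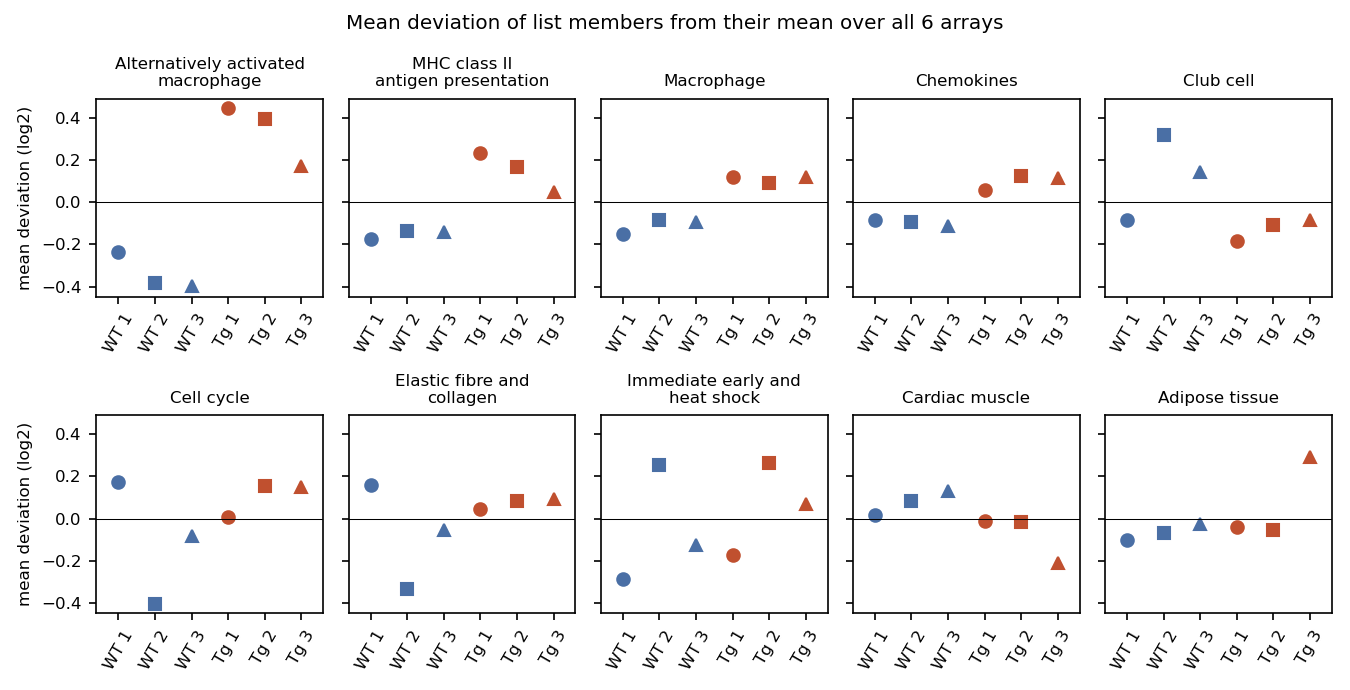
Mean deviation (log2) of the members of 10 gene lists from their mean over all 6 arrays, 1 point per array, with wild type in blue and Scnn1b-Tg in red. The 3 transgenic arrays lie above the 3 wild-type arrays for alternatively activated macrophage, MHC class II, macrophage and chemokine genes, wild type replicate 2 is lowest for cell cycle (-0.40) and elastic fibre and collagen (-0.33), and Scnn1b-Tg replicate 3 is highest for adipose tissue (0.29) and lowest for cardiac muscle (-0.21).

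Markers of other cell types gave 3 further calls. Cardiac muscle genes, which atrial-type muscle of pulmonary veins also expresses, had 14 of 16 members lower and a mean of -0.16 (adjusted p = 3.58e-05; adjusted p = 0.305 with an estimated correlation), with 0 past the threshold adjusted over the list alone. Myl7 gave -0.46 ± 0.17 (SE) and Myh6 -0.42 ± 0.11, and without Scnn1b-Tg replicate 3 Myl7 was -0.28 and the list mean -0.09 (adjusted p = 0.00731). Only 6 of the 16 listed red blood cell genes were measured. Of these 4 were lower, with a mean of -0.16 (adjusted p = 0.0246, and adjusted p = 0.380 with an estimated correlation). Adjusted over the list alone 1 passed, Bpgm at -0.36 ± 0.09, beside -0.46 ± 0.16 for Alas2. The red blood cell call ended without Scnn1b-Tg replicate 1 (Alas2 -0.27, mean -0.08, adjusted p = 0.111), wild type replicate 2 (adjusted p = 0.0503) or wild type replicate 3 (adjusted p = 0.195). B and plasma cell genes had 16 of 19 members higher and a mean of 0.11 (adjusted p = 0.0273; adjusted p = 0.603 with an estimated correlation), with 0 past the threshold adjusted over the list alone. Jchain gave 0.48 ± 0.27 and Pou2af1 0.22 ± 0.11, with Jchain at 0.13 without Scnn1b-Tg replicate 3 and Pou2af1 at 0.12 without wild type replicate 2. The B cell call ended without wild type replicate 2 (mean 0.03, adjusted p = 0.827), wild type replicate 1 (adjusted p = 0.0647), Scnn1b-Tg replicate 1 (adjusted p = 0.303) or Scnn1b-Tg replicate 3 (adjusted p = 0.0650). The mean of the B cell list was 0.18 without wild type replicate 3 and 0.17 without Scnn1b-Tg replicate 2.

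The lists of the gas-exchange surface were not called by camera with its preset correlation. Alveolar type 2 cell genes had 12 of 20 members higher with a mean of 0.04 (adjusted p = 0.441), led by Chil1 at 0.37 ± 0.09 (SE) and Hc at 0.26 ± 0.10, and the mean was -0.00093 without wild type replicate 1. Alveolar type 1 cell genes had 14 of 21 lower with a mean of -0.03 (adjusted p = 0.0964), with -0.23 ± 0.08 for the caveolin Cav2 and 0.17 ± 0.12 for the keratin Krt7, which was 0.05 without Scnn1b-Tg replicate 3. The alveolar type 1 mean turned to 0.01 without wild type replicate 3. The list passed in 4 of 16 alternatives, with adjusted p-values from 0.00689 to 0.953. Endothelial genes had 17 of 25 lower with a mean of -0.03 (adjusted p = 0.0690), with -0.33 ± 0.11 for the endothelin receptor Ednrb and 0.25 ± 0.14 for Edn1, which ran from 0.16 to 0.43 over single arrays left out. The endothelial mean turned to 0.02 without Scnn1b-Tg replicate 1 and to 0.0079 without wild type replicate 3. The list passed in 5 of 16 alternatives, with adjusted p-values from 0.000354 to 0.995. Smooth muscle and mesenchyme genes were split 11 to 11 with a mean of 0.01, against a downward direction in camera (adjusted p = 0.982). Msln gave 0.20 ± 0.11 and Cnn1 -0.20 ± 0.19, with ranges over single arrays left out of 0.11 to 0.31 and -0.39 to -0.02. The smooth muscle mean turned to -0.0029 after quantile normalization and -0.0085 after median centring. Adipose tissue genes had 9 of 13 higher with a mean of 0.13 (adjusted p = 0.217), led by Fabp4 and Adipoq (0.30 ± 0.25), and Adipoq was highest on Scnn1b-Tg replicate 3. Without that array Adipoq was -0.02 and the mean of the adipose list 0.02 (adjusted p = 0.956). The adipose list passed in 2 of 16 alternatives, with adjusted p-values from 0.0316 to 0.956. Skeletal muscle genes had 8 of 15 lower with a mean of -0.0099 (adjusted p = 0.623), with -0.14 ± 0.06 for Mb and -0.10 ± 0.09 for Tnnt3, which ran from -0.19 to -0.03 over single arrays left out. Thymus genes had a mean of -0.0020 and a downward direction in camera but a median of 0.02 (adjusted p = 0.685), with -0.22 ± 0.07 for Cd1d1 and 0.10 ± 0.09 for Cd4, which ran from 0.03 to 0.18. The 4 genes of the Y chromosome and Xist list gave a mean of -0.0038 (adjusted p = 0.871). Kdm5d gave 0.03 ± 0.04 and Uty -0.03 ± 0.06, both with mean intensities of 20.7 to 21.7 in each genotype, near the lowest values of the arrays. Over single arrays left out they ran from 0.02 to 0.06 and from -0.07 to 0.01.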

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

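Tests with 16 subtracted from every intensity and with both arrays that stood apart left out were chosen after seeing the data. The 1 called gene became 39 with the 6645 dimmest genes left out (9 changed at least 2-fold), 36 with an intensity trend and robust variance (4 at least 2-fold), 23 with 16 subtracted (14 at least 2-fold) and 6 without both arrays (4 at least 2-fold). The first 3 of these raised the total degrees of freedom from 6.99 to 10.6, 12.2 and 10.5; 16 genes were called by all 3, and of the 43 called by any 1 was lower, Tspan12. Leaving out arrays in turn gave 0 to 5 called genes and 0 to 2 at least 2-fold, with 0 only without wild type replicate 3. With 16 subtracted the log2 fold changes of dim genes were larger: 2.71 against 1.66 for Rnase2a (named after its value was seen), 2.24 against 1.49 for Slc26a4, 1.23 against 0.72 for Ccl24, 1.02 against 0.47 for Serpinb2, 0.90 against 0.41 for Egln3 and 0.80 against 0.46 for Mmp25. Quantile normalization, median centring, mean probe sets, all probe sets and array weights each called 1 gene. Scnn1b ranged from 3.20 to 3.53 over the arrays left out and was called in all alternatives but without wild type replicate 3 (adjusted p = 0.0559).

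The design fixed beforehand did not take replicate numbers as pairs, since nothing in the labels links samples of the same number. Correlations of deviations between such samples across genes were small (0.026 to 0.039), though above those of the other pairs between genotypes (-0.063 to 0.024). With the replicate block 3 genes were called, all at least 2-fold higher (Scnn1b, Chil3 and Chia1, the last 2 outside the naming rule), and 19 lists; the epithelial host defence list lost its call.

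Called lists numbered 15 to 21 against 17, except 0 with an estimated correlation and 7 with fry. No called list changed the sign of its mean, and 256 of 306 list results stayed past the threshold. Of 377 results for lists that were not called, 36 passed the threshold. For the named genes besides Scnn1b, 1226 of 1272 results kept both their sign and their side of it, 39 passed it, 7 turned in sign without passing, and 16 of 80 genes passed at least once.

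Signs turned only for genes and lists that were not called, and the cause was not tested. The mean of the ciliated list was -0.0074 after quantile normalization and -0.011 after median centring, and that of smooth muscle -0.0029 and -0.0085. With 16 subtracted thymus was 0.0072 and the Y chromosome and Xist list 0.010. Without both arrays Krt7 was -0.0078, Hspa1a 0.22, Adipoq -0.0020, interferon response 0.0069, smooth muscle -0.027 and skeletal muscle 0.022. Over the arrays left out in turn the ranges were -0.63 to 0.18 for Hspa1a, -0.068 to 0.013 for Uty, -0.16 to 0.0012 for Scnn1g, -0.021 to 0.48 for Adipoq, -0.029 to 0.036 for ciliated cells. For further lists they were -0.00093 to 0.071 for alveolar type 2, -0.060 to 0.012 for alveolar type 1, -0.013 to 0.26 for immediate early, -0.086 to 0.020 for interferon, -0.031 to 0.042 for smooth muscle, -0.12 to 0.016 for circadian, -0.031 to 0.0075 for skeletal muscle, -0.031 to 0.014 for thymus, -0.057 to 0.020 for endothelium and -0.026 to 0.022 for Y chromosome and Xist.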

Other observations

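The genes of the first paragraph, and Dbp, Arntl and Hspa1a below, were chosen after their values were seen, as were the tests on wild type replicate 2, on macrophage genes and on fat-cell genes; the tests on growth genes and on other splits of the arrays were set before their results were seen. The growth question itself came from the spread of the wild-type arrays, in which Peg3 had been seen and was left out of the test, and the shares over other genes were added after the result.

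Beyond the genes named by the rule, 6 more of the 14 that were at least 2-fold higher at any p are given here as values, since none but Scnn1b passed limma's test over all genes. Of these 6, Retnla, Chil3 and Arg1 are on the alternatively activated macrophage list and Chia1, Rnase2a and Gapt on no list, and no shared theme was tested among them. Chia1, the acidic mammalian chitinase, gave a log2 fold change of 1.90 ± 0.31 (SE, adjusted p = 0.190), and the chitinase-like Chil3 1.34 ± 0.19 (adjusted p = 0.146). Rnase2a, an eosinophil-type ribonuclease, gave 1.66 ± 0.20, and Arg1, the arginase of alternatively activated macrophages, 1.14 ± 0.14 (adjusted p = 0.109 each). Retnla, a resistin-like protein, gave 1.54 ± 0.34 (adjusted p = 0.387) and Gapt 1.21 ± 0.21 (adjusted p = 0.225). Rnase2a, Chil3, Arg1, Pla2g7, Ms4a4a, C3ar1 and the complement gene C1qb were among the 16 genes called with the 6645 dimmest genes left out, with an intensity trend and robust variance, and with 16 subtracted alike. Scgb1a1, the main secretory protein of club cells, gave -0.31 ± 0.07 and passed adjusted over the club cell list alone (adjusted p = 0.0261) but not over all genes (adjusted p = 0.398). The mucin genes Muc5ac (0.37 ± 0.09) and Muc4 (0.35 ± 0.08) were the 2 members of the goblet list that passed adjusted over the list alone (adjusted p = 0.0455 each).

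Cell cycle and matrix genes were higher in Scnn1b-Tg mainly against wild type replicate 2. Without that array the camera adjusted p was 0.171 for the cell cycle list and 0.512 for the elastic fibre and collagen list, while both calls held when each other array was left out. Of 15 growth genes, most of them imprinted, 9 (60%) ran from high to low in the order wild type replicate 1, 3, 2. That order held for 19.2% of all other genes. It held for 31.4% of the 3045 others that spread at least as much between the wild-type arrays as the median growth gene. Some of the 9 differed clearly, such as Mest (8.37, 8.08 and 7.57), and some by little, such as the dim Asb4 (4.74, 4.66 and 4.64). Igf2 (5.89, 5.97 and 5.85) and Dlk1 (5.74, 5.77 and 5.68) were not in that order, and Cdkn1c ran in reverse (7.98, 8.05 and 8.20). Wild type replicate 2 also differed outside growth, on single genes and on the club cell list. Log2 values were 7.72 for Dbp (6.70 and 6.47 on replicates 1 and 3), 5.58 for Arntl (6.59 and 6.71) and 7.72 for Hspa1a (6.11 and 6.49). The club cell list, picked here after its values were seen, had mean deviations of 0.32, 0.14 and -0.09 on wild type replicates 2, 3 and 1. Without replicate 2 its mean was -0.15, against -0.25 with all arrays, and the camera call held (adjusted p = 6.02e-07). Growth stage is thus only 1 candidate explanation, as a hypothesis. The growth genes are not independent, no age is given in the labels, and an effect of the transgene on growth was not tested.

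The macrophage-associated lists could rise for several reasons. The test here concerned only more alveolar macrophages against macrophages that changed state. The median log2 fold change was 0.11 for 10 genes typical of alveolar macrophages, 9 of which the macrophage list also holds, and 0.40 for 19 alternative activation genes. The difference of -0.29 had a permutation p of 0.0764 across genes. That test treats genes as independent, which genes of 1 cell type are not, and whole-lung RNA does not separate cell number from cell state. These explanations therefore cannot be told apart here. Marco (0.01), Krt79 (-0.14) and Fabp5 (-0.01) had values near or below 0, while Itgax (0.53) and Siglecf (0.39) were higher. Itgam (0.91) and Adgre1 (0.76), the largest values of the macrophage list, are not among the 10 genes. Eosinophils, which also carry Siglecf, and macrophages other than alveolar ones remain further sources that were not tested.

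Genes of fat cells were high on Scnn1b-Tg replicate 3, where Car3 lay 3.45 above the mean of the other arrays on the log2 scale, Fabp4 1.56, Adipoq 0.94 and Retn 0.70. A candidate explanation is fat tissue taken along with that lung. Of 10 further fat-cell genes 4 (40%, against 22.2% of all other genes) were highest on that array, among them Pck1 and Plin1 but not Cidec or Lipe, which lies between the bounds set for and against it. Of those 4, Ucp1 was dim and lay only 0.09 above the mean of the other arrays (log2 value 4.66 on that array). Lep (4.63) and Cidea (4.77), which were not highest there, were dim as well. Contamination and a difference within that lung cannot be told apart here, since fat-cell genes could be high on that array under either, whatever the share.

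With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1 called gene and the highest other split 0, and the real split was 1 of 10 with as many. For lists the real split gave 17 calls and the highest other 14, and again 1 of 10 splits gave as many.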
